A study of Mus musculus with 28 samples.

How the data were processed

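The files hold 1 count per gene and library, as deposited. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.0 and cutadapt, checked with FastQC and aligned to the mouse genome (GRCm38, also given as mm10) with STAR 2.7.0e, and DESeq2 1.26.0 was used on the counts. The program that counted reads, the gene annotation and the strand setting are not stated. Per the labels, RNA was taken up in TRIzol, messenger RNA was selected by poly(A), and libraries were made with the NEB Ultra II non-directional kit. The stated aim of the series was to compare expression in the Slc1a3, Dlx1 and Aspm lineages of basal cells.

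All 28 libraries in 12 groups were used. The 55536 gene identifiers all matched GENCODE M21, 33440 had a count in any library, and 118 shared a symbol with an identifier of higher count and were kept by identifier. Lists, comparisons, their tests and the first set of alternatives were fixed before the data were examined, whereas most tests of explanations, the divisions of libraries and the fits of lines together came after. Counts were scaled by the trimmed mean of M values (TMM), and genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 17493. A single quasi-likelihood model with 1 mean per group was fitted in edgeR 4.0.16 (robust), with 16 residual degrees of freedom and a biological coefficient of variation of 0.280. It gave 16 comparisons and 6 background comparisons between the lines' totals. Genes with a Benjamini-Hochberg adjusted p under 0.05 passed. Other software was R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. Log2 CPM for the principal components used a prior count of 2.

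Of 35 gene lists, written from general knowledge of skin, 34 had at least 5 members tested. Each was tested by limma's camera with a fixed correlation of 0.01 between genes, and again with a correlation estimated from the data, adjusted over the 34 lists of a comparison. With the estimated correlation 2 lists passed for tail Slc1a3+ cells against their total, 1 each for tail Aspm+ and Dlx1+ cells, 3 for tail Aspm+ against Dlx1+ cells, 6 for total IFE between sites, 1 each for Slc1a3+ and Aspm+ cells between sites, and 0 elsewhere by camera. Counts "adjusted over the list alone" take the members' p-values by themselves. Members are printed only for lists described, which are bulge and germ, fibroblast, BMP and TGF-beta, mitosis and G2, differentiation, upper follicle and sebaceous, ribosome, oxidative phosphorylation, antioxidant, stress, posterior Hox, anterior and central Hox, interferon response, scale-type hard keratins and immediate early genes. The list medians printed for these comparisons did not change with members at 0 counts set to their bound except where both are given. The limma test fry was run beside camera and is not printed.

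The 4 genes naming the lines are given as group means and ranges over comparisons. Other genes were named by a fixed rule. They had to pass, to be fully separated between the libraries of the 2 groups, to hold at least 5 CPM in the higher group, and to carry no name of a predicted gene. Of these the largest changes were taken, up to 10 each way in 8 main comparisons and 4 each way in the others, and the interaction was spared the separation condition. For lists that passed, up to 4 members with the lowest p were added. Where a group had 0 counts the fold is a bound against 3 counts per library, and with 1 to 3 counts a ratio is given with its interval.

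Labelled and total libraries with the same line and number were taken as sorted from 1 skin, after a check over 10376 genes with a mean log2 CPM of at least 2. In 14 of these pairs the deviations from the group means correlated at r = 0.18 to 0.689, whereas libraries with the same number from different lines gave -0.117 to 0.343. In groups of 2 libraries both pairs of a line give the same r by construction. The back Slc1a3 pairs, at 0.18 to 0.216, and the tail Aspm pairs, at 0.321, lay within the range between lines. The back K14 pairs, at 0.362, lay just above it. The paired model, called replicate block, adds 1 term per pair (8 residual degrees of freedom, variation 0.185), and it is given beside the results for labelled cells against their total. The labels do not state the pairing.

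The model was tested on simulated counts of 17493 genes with 50 changed per size. At 1.5-fold, 2-fold, 4-fold and 8-fold it recovered 3, 27, 47 and 49 for back Slc1a3+ against total (5 false among 147 called), 4, 24, 47 and 49 for tail Slc1a3+ against total (5 of 135), and 8, 22, 45 and 49 for tail Slc1a3+ against Dlx1+ (3 of 139). A shifted list of 20 genes was found each time by camera with the fixed correlation, and 0 of 20 unchanged lists passed. Genes were drawn independently of each other, and genes of low level were not changed. The simulation therefore cannot judge the fixed correlation for lists whose genes move together.

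The alternatives were scaling by DESeq2 size factors or library totals, no low-count filter (33440 genes), a strict filter of 1 CPM, a minimum of 2-fold, DESeq2's test, limma-voom, a fit of only the compared groups, the replicate block, subtraction of each line's or site's own total, and leaving out each library. Added after the data were seen were leaving out the back Slc1a3 total library of few genes, the block without it, and the subtraction with the block. A test for values far from their group was run on 98 values of libraries and named genes. The 3 lines of a site were also fitted together, labelled against total, with the block. Isoforms, single reads and cell types within a library could not be studied from these files, and the shared sequence of overlapping genes was not resolved.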

Results

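RNA was sequenced from interfollicular epidermis (IFE), the skin between the hair follicles, of mice from 4 lines. In each line an inducible Cre recombinase (CreER), carried under the name Slc1a3, Aspm, Dlx1 or K14 (keratin 14, the gene Krt14), is combined with a tdTomato reporter at the Rosa locus. Tamoxifen was given on 5 consecutive days between postnatal days 30 and 34, and skin was taken 2 weeks later, at postnatal day 49, in the resting phase of the hair cycle. For each line and site the labels give the cells positive for the line's name, called labelled cells here, and the total IFE cells. Back skin holds Slc1a3+ and its total (3 libraries each), Aspm+ and its total (3 each) and K14+ and its total (2 each), 16 libraries in all. Tail skin holds Slc1a3+, Aspm+ and Dlx1+ cells and their totals (2 each), 12 libraries in all.

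Library totals ran from 7738262 to 37670589 counts, with a median of 20193387. Levels are given in CPM, counts scaled to the size of the library, with the standard deviation (SD) of the libraries. Changes are log2 fold changes with their standard error (SE) from edgeR's quasi-likelihood test, with p adjusted by the Benjamini-Hochberg method over the 17493 genes tested. The labels do not state whether libraries come from separate animals, so p-values measure the spread between these samples. Intervals and floors cover counting error only. The libraries were not strand-specific, so a gene that overlaps another, or a near-identical copy, is uncertain.

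The site separated the libraries before anything else. The first principal component held 63.1% of the variance, with back libraries between -56.7 and -35.7 and tail libraries between 39.5 and 69.5. The next component held 10.5%, and on it the back Slc1a3 total replicate 4 lay at 94.8 while the other libraries lay between -16.8 and 11.3. That library had the lowest total, 14436 genes with a count and 0.208% mitochondrial counts. Thinned to its depth, the other 27 libraries held 17207 to 19543 genes. Libraries of 1 group correlated at r = 0.947 to 0.987 across genes, except that this library reached only 0.856 and 0.866 with its group (genes are not independent replicates).

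**Figure D1:**
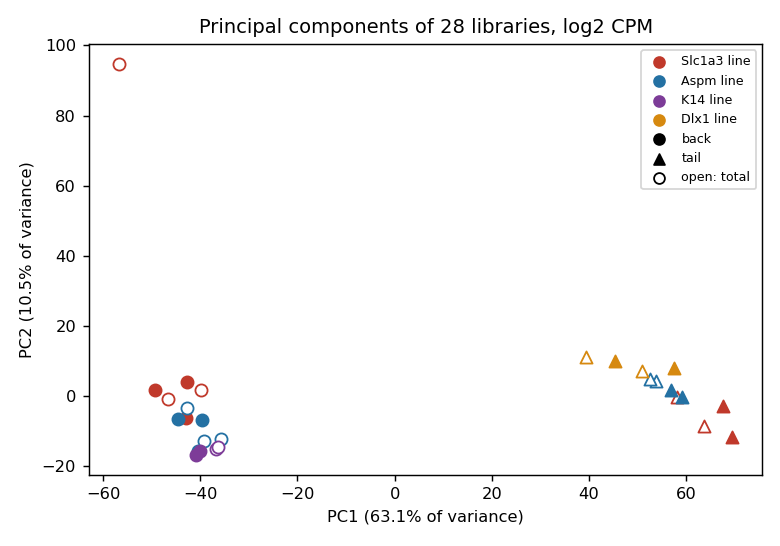
Positions of the 28 libraries on the first 2 principal components of log2 CPM, with the percent of variance on each axis and groups by colour and shape. Back libraries lie between -56.7 and -35.7 and tail libraries between 39.5 and 69.5 on the first component, and back Slc1a3 total replicate 4 lies apart at 94.8 on the other.

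The 4 genes that name the lines were read in every group, since the labelled cells were marked through them 2 weeks earlier. Slc1a3 (ENSMUSG00000005360, GRCm38 chromosome 15, 8634124 to 8710764), a glutamate and aspartate transporter, was higher in tail Slc1a3+ cells (19.0 CPM, SD 1.94, n = 2) than in their total (8.01, SD 0.648, n = 2), a log2 change of 1.25 (SE 0.273, adjusted p = 0.0279). In back skin it measured 25.6 CPM (SD 3.19, n = 3) in Slc1a3+ cells and 18.1 (SD 3.01, n = 3) in their total, a log2 change of 0.51 that did not pass (adjusted p = 0.837). Dlx1 (ENSMUSG00000041911, chromosome 2, 71528113 to 71533981), a homeobox transcription factor, measured 8.94 CPM (SD 0.565, n = 2) in tail Dlx1+ cells and 7.80 (SD 0.730, n = 2) in their total (log2 0.20, adjusted p = 1). Group means of Dlx1 lay between 7.80 and 11.2 CPM in all 6 tail groups and between 0 and 1.08 in the 6 back groups.

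Aspm (ENSMUSG00000033952, chromosome 1, 139454772 to 139494091), a spindle pole protein of dividing cells, measured 16.6 CPM (SD 4.79, n = 3) in back Aspm+ cells and 14.7 (SD 6.51, n = 3) in their total, and 18.3 (SD 0.481, n = 2) and 22.2 (SD 2.12, n = 2) in tail. Neither difference passed (log2 0.19 and -0.28, adjusted p = 1 for both). Krt14 (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548), a keratin of basal cells, measured 19930 CPM (SD 690, n = 2) in back K14+ cells and 18850 (SD 653, n = 2) in their total (log2 0.08, adjusted p = 1). Over the 12 comparisons within a site, Slc1a3 ran from -0.39 to 1.25 with 1 passing, Aspm from -1.02 to 0.44 and Krt14 from -0.83 to 0.69, both with 0 passing by edgeR at these settings (in others Aspm passed for 1 comparison and Krt14 for 3). The lowest adjusted p was 0.104 for Aspm, 0.0766 for Krt14 and 0.119 for Dlx1, for which no range is given because back skin lies near 0 counts.

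**Figure D2:**
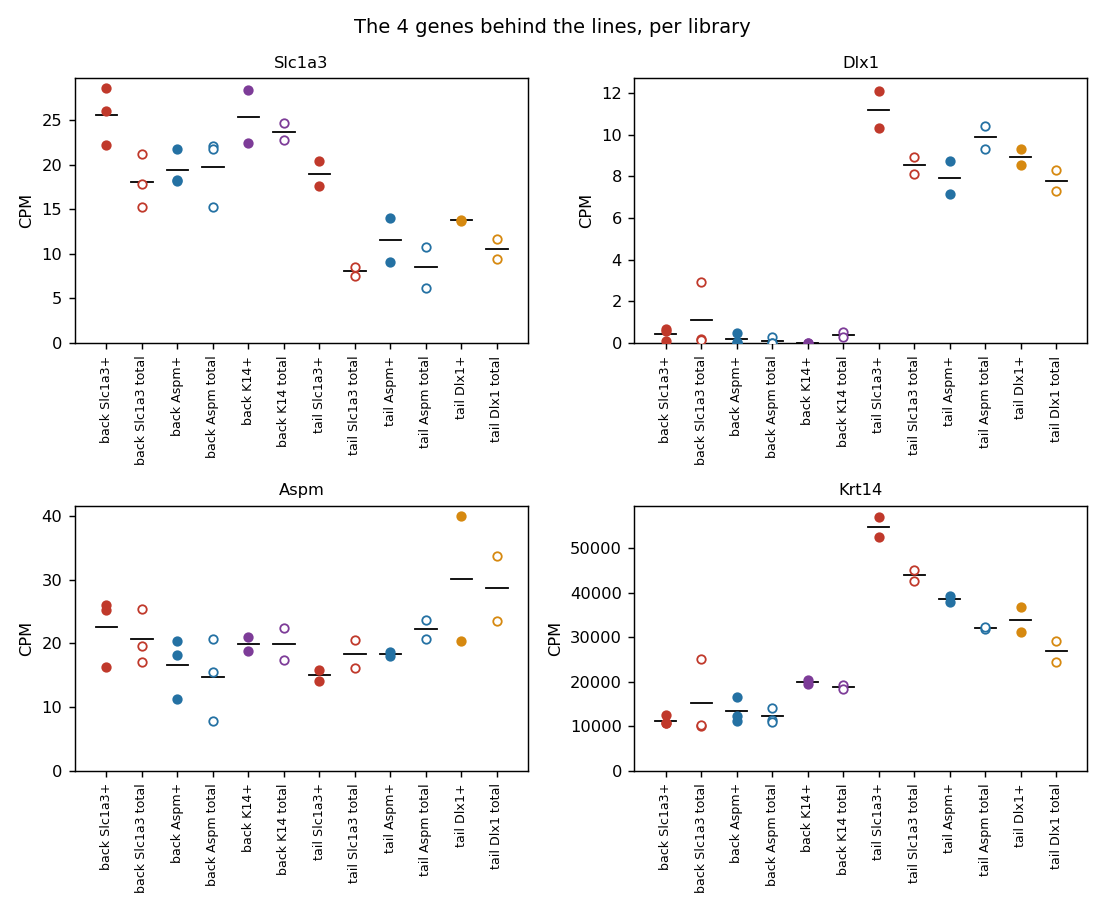
Level of Slc1a3, Dlx1, Aspm and Krt14 in each library (points, CPM on a linear axis) with the mean of each of the 12 groups (bars). Slc1a3 is higher in tail Slc1a3+ cells (mean 19.0 CPM) than in their total (8.01 CPM), and Dlx1 lies above 7 CPM in tail groups only.

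Which genes set Slc1a3+ cells of back skin apart from the total IFE was asked next. Most of the genes that passed were lower in the labelled cells. Hmcn1, which encodes an extracellular matrix protein, measured 1.89 CPM (SD 0.689, n = 3) in Slc1a3+ cells and 21.1 (SD 5.87, n = 3) in the total, a log2 change of -3.48 (SE 0.432, adjusted p = 1.81e-04). Ltbp1, a binding protein of latent TGF-beta, measured 2.13 CPM (SD 0.931) and 11.5 (SD 3.10), a change of -2.45 (SE 0.286, adjusted p = 9.90e-05). Tnc, which encodes tenascin C, fell by 2.03 on the log2 scale, Kif26a by 3.59, Kif26b by 3.06, Cacna2d2 by 2.21, Shroom3 by 1.91, Arhgef17 by 1.79 and Scube2 by 1.73. Sostdc1, a secreted inhibitor of BMP and Wnt signalling, measured 45.7 CPM (SD 28.8) against 130.2 (SD 32.8), a change of -1.51. Of the 3 genes that were higher, Gt(ROSA)26Sor, an annotated antisense transcript at the locus that carries the reporter, rose from 10.1 CPM (SD 4.97) to 29.7 (SD 4.48), a change of 1.51 (SE 0.294, adjusted p = 0.0354). Tmem246 rose by 0.77, and Rbp7, named after its values were seen, by 5.60 (SE 1.07). Rbp7 fell short of the naming rule, in level or in separation of the libraries.

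In all, 19 genes passed in this comparison, 3 higher and 16 lower, and 988 had an unadjusted p under 0.05. Of the 20 hair follicle bulge and germ genes, 15 were negative, 1 fell over all genes and 3 when adjusted over the list alone. The list's median change was -0.43 and its camera adjusted p = 8.39e-04, which became adjusted p = 0.514 with an estimated correlation. The count was 135 without a low-count filter, 43 by DESeq2's test, 9 by limma-voom, 0 with only the compared groups in the fit, 62 (11 higher, 51 lower) with labelled and total libraries paired by replicate number, and 88 with this pairing and without the total library of few genes. It was 11 without Slc1a3+ replicate 1, 9 without Slc1a3+ replicate 2 and 9 without total replicate 2, while Hmcn1, Kif26b, Ltbp1 and Shroom3 passed with each of the 6 libraries left out.

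The same question was put to the back Aspm+ cells. The 30 genes of mitosis and G2, which drive and mark cell division, lay higher for 23 members, with a median change of 0.18 and 0 members passing over all genes or adjusted over the list alone. Mki67, a marker of cycling cells, measured 111.5 CPM (SD 75.7, n = 3) in Aspm+ cells and 74.5 (SD 51.2, n = 3) in their total. The list's camera adjusted p = 0.00344 became adjusted p = 0.673 with an estimated correlation. Of the 20 hair follicle bulge and germ genes 15 were negative, with a median of -0.36 and 2 lower when adjusted over the list alone (camera adjusted p = 5.79e-04, adjusted p = 0.260 with an estimated correlation). Lists of other cells went both ways. Endothelium and mural genes had a median of -2.45, or -1.62 with members at their bound, adipocyte genes -1.94 and Merkel cell genes 0.37, or 0. Of the 27 genes of the BMP and TGF-beta pathway 20 were negative and 2 were lower when adjusted over the list alone (camera adjusted p = 2.21e-05), and its adjusted p = 0.0690 with an estimated correlation became 0.0322 with the libraries paired. By edgeR 0 genes passed, 382 had an unadjusted p under 0.05, and the count was 2 by DESeq2's test, 0 by limma-voom, 27 without a low-count filter, and 8 with pairing and without the total library of few genes.

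K14+ cells, marked through a keratin of the whole basal layer, differed from the back total in 1 gene, Ltbp1, which measured 0.488 CPM (SD 0.00311, n = 2) and 5.37 (SD 0.0905, n = 2), a log2 change of -3.45 (SE 0.398, adjusted p = 1.61e-04). Of the 20 hair follicle bulge and germ genes 15 were negative, with a median of -0.32 and 2 lower when adjusted over the list alone. The list's camera adjusted p = 1.71e-06 became adjusted p = 0.108 with an estimated correlation, and 0.0141 with the libraries paired. The BMP and TGF-beta list (27 genes, 1 lower, 3 lower when adjusted over the list alone) had a median of 0.02, a mean of -0.53 and a test pointing down, and its adjusted p with an estimated correlation moved from 0.108 to 0.0342 with pairing. The 14 posterior Hox genes, which specify tail-ward positions, had 10 negative members and 0 passing at levels close to 0, and moved from 0.0939 to 0.0210 in the same way. A total of 376 genes had an unadjusted p under 0.05, and the count was 42 without a low-count filter, 12 by DESeq2's test, 0 by limma-voom, 11 with only the compared groups, 18 (0 higher, 18 lower) with pairing and 39 with pairing and without the total library of few genes. Without K14+ replicate 1 the call of Ltbp1 was lost and 0 genes passed.

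In tail skin, too, most genes that passed were lower in Slc1a3+ cells than in their total. Lrig1, a marker and growth restraint of epidermal stem cells, measured 10.6 CPM (SD 1.27, n = 2) in Slc1a3+ cells and 83.3 (SD 5.81, n = 2) in the total, a log2 change of -2.98 (SE 0.419, adjusted p = 3.58e-04). Susd2 measured 3.43 CPM (SD 0.576) and 41.4 (SD 2.18), a change of -3.59 (SE 0.214, adjusted p = 2.58e-10). Il20ra, a receptor chain for cytokines of the interleukin 20 family, changed by -3.37 (SE 0.304, adjusted p = 4.88e-07), and Rasgrp1, an activator of Ras, by -4.43 (SE 0.534, adjusted p = 5.38e-05). Fst, an activin antagonist, fell by 4.14, Stra6, a retinol transporter, by 4.67, Dpysl3 by 3.90, Pappa by 3.84, Col8a1 by 3.48 and Alox12e by 2.99. Igfbp3, a binding protein of insulin-like growth factors, rose from 118 CPM (SD 16.6) to 268 (SD 52.9), a change of 1.19, Gipc2 rose by 2.05 and Slc1a3 by 1.25.

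Genes of the hair follicle bulge and germ, the stem cell region of the follicle, were lower in the tail Slc1a3+ cells. Of the 20 members 18 were negative, 4 fell over all genes, 13 were lower and 1 higher when adjusted over the list alone, and the median change was -1.72. Sox9, a transcription factor of bulge stem cells, changed by -2.36, Postn by -2.46, Sostdc1 by -1.89 and Col6a1 by -1.57, with adjusted p of 0.00214, 0.0350, 0.00352 and 0.00179. The camera adjusted p was 1.36e-19, and 0.00192 with an estimated correlation. Of the 12 fibroblast markers 1 fell and 3 were lower when adjusted over the list alone (adjusted p = 0.00372, and adjusted p = 0.0389 with an estimated correlation, which became 0.0876 with pairing). The 1 that fell was Col6a1, which is also on the bulge and germ list, so these lists are not independent.

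In all, 90 genes passed in tail Slc1a3+ cells, 3 higher and 87 lower, with 1004 at an unadjusted p under 0.05. The count was 276 without a low-count filter, 195 by DESeq2's test, 52 by limma-voom, 261 (24 higher, 237 lower) with pairing and 523 with pairing and without the back total library of few genes. It was 29 and 32 without Slc1a3+ replicate 1 or 2 and 49 and 51 without total replicate 1 or 2. Susd2, Il20ra, Rasgrp1, Fst, Dpysl3 and Lrig1 passed with each of the 4 libraries left out, whereas Slc1a3, Igfbp3, Col8a1 and Postn lost their calls with any of them. Over all 14 settings, Il20ra, Rasgrp1 and Fst each lost their call in 1.

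Aspm+ and Dlx1+ cells of tail skin were also low in bulge and germ genes against their totals. In Aspm+ cells 19 of the 20 members were negative, 1 fell and 5 were lower when adjusted over the list alone, with a median of -0.72 (camera adjusted p = 1.16e-15, and 0.00643 with an estimated correlation). The gene that fell was Grem1, a BMP antagonist, with 0 counts in both Aspm+ libraries and 6.10 CPM (SD 0.911, n = 2) in the total, at least 36.7-fold lower against a floor of 3 counts per library (adjusted p = 0.00942). In Dlx1+ cells 18 of the 20 were negative, 0 passed over all genes and 10 were lower when adjusted over the list alone, with a median of -1.24 (camera adjusted p = 6.24e-28, and 2.64e-04 with an estimated correlation). Grem1 measured a log2 change of -3.75 there (adjusted p = 0.119), Cd34, a bulge marker, -3.40, Lhx2, a bulge transcription factor, -2.58 and Sox9 -1.51. The 34 genes of spinous and granular differentiation had 26 positive members in Aspm+ cells and 0 passing by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.00688), and their adjusted p = 0.474 with an estimated correlation became 0.0451 with pairing.

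Grem1 was the 1 gene that passed in tail Aspm+ cells, and 423 had an unadjusted p under 0.05. The count was 26 without a low-count filter, 5 by DESeq2's test, 0 by limma-voom, 3 with only the compared groups, 6 (0 higher, 6 lower) with pairing and 41 with pairing and without the back total library of few genes, and it was 0 without either Aspm+ library. In tail Dlx1+ cells 0 genes passed by edgeR, and 446 had an unadjusted p under 0.05. The count was 34 by DESeq2's test, 29 by limma-voom, 95 without a low-count filter, 12 with only the compared groups, 3 scaled by library totals, 15 without the back total library of few genes, 81 (1 higher, 80 lower) with pairing, 212 with pairing and without that library, and 2 without total replicate 2.

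**Figure D3:**
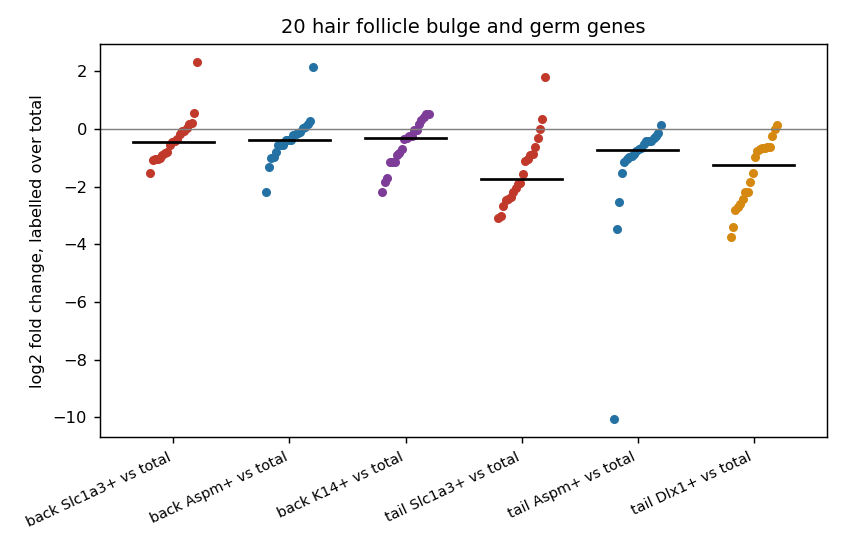
Log2 fold change of each of the 20 hair follicle bulge and germ genes (points) in labelled cells against their total, for the 3 back and 3 tail lines, with the median as a bar. Tail medians are -1.72, -0.72 and -1.24 against -0.43, -0.36 and -0.32 in back, and the point near -10 is the fitted value of Grem1, which has 0 counts in tail Aspm+ cells.

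Labelled cells of different lines were then compared within a site, each beside the same comparison of the lines' totals, which gives the background of the lines. In back skin, Slc1a3+ cells held more of Igfbp3 (1630 CPM, SD 209, n = 3) than Aspm+ cells (735.8, SD 58.7, n = 3), a log2 change of 1.15 (SE 0.196, adjusted p = 0.00864). Nr4a1, an immediate early nuclear receptor, rose by 2.20, Tbx3, a transcription factor, by 1.70, Zc3h12a by 1.15 and Ndufa4l2 by 1.07. Lower in Slc1a3+ cells were Hmcn1 (1.89 against 15.3 CPM, SD 0.689 and 4.22, log2 -3.01), Kif26b (-2.92), Defb1, a defensin (-2.59), Dpysl3 (-2.55), Ltbp1 (-2.46), Hpgd (-1.96), Cacna2d2 (-1.80), Sostdc1 (-1.71), Fkbp5 (-1.70) and Tent5b (-1.47). All 28 genes of the cytosolic ribosome were negative, 0 passing over all genes and 23 lower when adjusted over the list alone, with a median of -0.48 (camera adjusted p = 4.82e-23, adjusted p = 0.560 with an estimated correlation). The totals of the 2 lines gave -0.35 for the same median.

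Between back Slc1a3+ and Aspm+ cells 28 genes passed, 8 higher and 20 lower, with 1584 at an unadjusted p under 0.05. The lines' totals differed in 2 genes, Nr4a1 (2.25) and Defb1 (-1.82), both with adjusted p = 0.0403, and 24 of the 28 genes had the same sign in the totals. With each line's own total subtracted 0 genes passed, and Nr4a1 and Tent5b changed sign (-0.05 and 0.10), and 6 passed when the subtraction was paired, among them Hmcn1 (-3.17), Kif26a (-2.70) and Igfbp3 (1.06). The count was 255 without a low-count filter, 161 by DESeq2's test, 4 with only the compared groups and 115 without the total library of few genes, and 12, 14 and 9 without Slc1a3+ replicate 2, Slc1a3+ replicate 4 or Aspm+ replicate 4. Of the genes named, Hmcn1, Kif26b, Defb1, Ltbp1 and Sostdc1 passed with each library left out. With libraries scaled by their totals, 13 of 24 genes were higher.

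Against back K14+ cells, the Slc1a3+ cells held more Cyp27a1, a sterol hydroxylase (log2 4.97), Rab6b (4.21), Cyp1b1, a detoxifying cytochrome (3.50) and Adrb3 (3.31). Gypc, a membrane glycoprotein, measured 0.114 CPM (SD 0.198, n = 3) in Slc1a3+ cells and 44.2 (SD 3.60, n = 2) in K14+ cells, a change of -8.49 (SE 0.844, adjusted p = 3.90e-05). Esr1, the estrogen receptor alpha, changed by -2.71, Vcp-rs, a Vcp-related sequence, by -2.41, and the pseudogene Ywhaq-ps1, with 0 counts in Slc1a3+ cells, was at least 30.8-fold lower. CreER is not among the counted genes. Whether it adds to the counts of Esr1, here or between Aspm+ and K14+ cells, was not tested. Of the 28 ribosome genes 12 were lower and 27 when adjusted over the list alone, with a median of -0.69 (Rps19 -0.73, Rpl32 -0.89). Of the 27 oxidative phosphorylation genes 8 were lower and 21 when adjusted over the list alone, with a median of -0.57. Their camera adjusted p of 8.58e-24 and 4.15e-15 both became adjusted p = 0.446 with an estimated correlation, and the totals of the 2 lines gave medians of -0.68 and -0.59.

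In this comparison 489 genes passed, 191 higher and 298 lower, with 3301 at an unadjusted p under 0.05. The lines' totals differed in 1357 genes, 484 of the 489 had the same sign there and 338 passed there too. Gypc measured 0.0114 CPM in the Slc1a3 total and 46.9 in the K14 total, and Esr1 differed by -2.89. With each line's total subtracted 0 genes passed (edgeR, paired or not), and Gypc (2.57, from levels near 0), Esr1 (0.18) and Vcp-rs (0.12) turned. The count was 142 at a minimum of 2-fold, 979 without a low-count filter, 1258 by DESeq2's test, 1598 with only the compared groups and 1403 without the total library of few genes, and 91, 123, 9 and 10 without Slc1a3+ replicate 2, Slc1a3+ replicate 4, K14+ replicate 1 or K14+ replicate 4. Gypc and Esr1 passed with any library left out, and the other named genes did not. Scaled by library totals, 402 genes were higher and 97 lower, by DESeq2 size factors 227 and 190.

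Back Aspm+ cells differed from K14+ cells in part by the same names. Ltbp1 was higher in Aspm+ cells (11.7 CPM, SD 3.57, n = 3, against 0.488, SD 0.00311, n = 2), a log2 change of 4.57 (SE 0.389, adjusted p = 4.55e-07), and Hmcn1 by 4.14, Adgrl3 by 4.93 and Cyp27a1 by 5.29. Lower were Gypc (-8.35), Esr1 (-4.11), Nr4a1 (-2.10) and Baiap2l1, which measured 48.5 CPM (SD 3.70) and 786.7 (SD 36.3), a change of -4.02. The Aspm total held 0 CPM of Gypc and the K14 total 46.9, and the totals differed by -3.52 in Esr1. Of the 20 bulge and germ genes 2 were higher, and 6 when adjusted over the list alone, with a median of 0.81 (camera adjusted p = 7.31e-06, adjusted p = 0.180 with an estimated correlation) and 1.01 between the totals. In all 35 genes passed, 29 higher and 6 lower, with 1402 at an unadjusted p under 0.05, the totals differed in 12, and 34 of the 35 had the same sign there.

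With each line's total subtracted 0 genes passed in that comparison (edgeR, paired or not), and Gypc turned to 4.66 from levels near 0. Over all settings, these included, the change stayed at 2.52 or more for Ltbp1, 2.57 for Hmcn1 and 2.83 for Adgrl3. Esr1 and Baiap2l1 came as near to 0 as -0.46 and -0.15. The count was 342 without a low-count filter, 151 by DESeq2's test, 12 by limma-voom and 60 without the Slc1a3 total library of few genes, and 16, 8 and 13 without Aspm+ replicate 1, K14+ replicate 1 or K14+ replicate 4. Ltbp1, Hmcn1, Gypc and Esr1 passed with each library left out.

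Slc1a3+ and Dlx1+ cells of tail skin carry the names of 2 different epidermal lineages, and the genes with the largest changes went both ways. Higher in Slc1a3+ cells were the cornified envelope genes Sprr1b (3.36) and Sprr1a (2.88), the protease inhibitor genes Wfdc18 (4.66) and Serpinb3d (4.14), Slurp1 (4.08), Hsd3b6, a steroid dehydrogenase (3.65), Cidea, a lipid droplet protein (2.91), and Rarres1, a retinoic acid responsive gene (4.07). Wfdc17 measured 111 CPM (SD 30.7, n = 2) in Slc1a3+ and 9.89 (SD 1.94, n = 2) in Dlx1+ cells, a change of 3.49 (SE 0.424, adjusted p = 5.94e-05), and Far2, a fatty acyl-CoA reductase, 89.9 (SD 19.5) and 12.4 (SD 3.87), a change of 2.85. Susd2 measured 3.43 CPM (SD 0.576) and 41.1 (SD 1.09), a change of -3.58 (SE 0.214, adjusted p = 2.64e-10). Rasgrp1 changed by -4.81, Fst by -3.86, Col8a1 by -3.80, Dpysl3 by -3.72, Pappa by -3.66, Stra6 by -3.55, Il20ra by -3.22, Krt7, a keratin of simple and glandular epithelia, by -2.96 and Rnf213 by -2.95.

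All 28 ribosome genes were positive in tail Slc1a3+ against Dlx1+ cells, 24 were higher over all genes and 28 when adjusted over the list alone, with a median of 0.88 (Rps2 1.32, Rplp1 1.10, Rps19 0.95). Of 27 oxidative phosphorylation genes 12 were higher and 22 when adjusted over the list alone, with a median of 0.71 (Uqcrq 1.19). Of 25 antioxidant genes 8 were higher, and 10 higher and 1 lower when adjusted over the list alone (Mt1 1.41, Prdx1 0.87, Gpx1 0.74). Of 34 differentiation genes 6 were higher and 8 when adjusted over the list alone, with a median of 0.72, or 0.58 with members at 0 counts set at their bound (Krt77 2.21, Elovl4 1.85, Mt4 1.47). Of 21 genes of the upper follicle and sebaceous gland 7 were higher and 1 lower, and 8 and 1 when adjusted over the list alone. Camera adjusted p ran from 2.11e-27 for the ribosome to 3.94e-04 for the antioxidant list, and became adjusted p = 0.287 with an estimated correlation for the antioxidant list and adjusted p = 0.241 for the other 4 lists. In all 13 lists passed by camera with the fixed correlation. Among lists not described, Langerhans and myeloid genes had a median of 2.16, or 1.54 with members at their bound. Anagen matrix and inner root sheath genes had 1.65, or 1.33, and Wnt pathway genes -0.11. The totals of the 2 lines gave medians of 0.83 for the ribosome, 0.61 for oxidative phosphorylation, 0.28 for differentiation and 0.55 for the upper follicle list, whose median in labelled cells was 1.12. With each line's total subtracted the medians of these lists were 0.053, 0.057, 0.031 and -0.072 in the same order.

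Of all genes, 957 passed, 404 higher and 553 lower, with 3696 at an unadjusted p under 0.05. The totals differed in 335 genes (171 higher, 164 lower), and 943 of the 957 had the same sign there, 244 of them passing in both. Rarres1 and Wfdc17 differed by 4.59 and 3.93 between the totals, whereas Susd2 (-0.46, adjusted p = 0.176) and Il20ra (-0.13) did not pass there. With each line's total subtracted 4 genes passed, all lower, Susd2 (-3.12), Il20ra (-3.10), Col23a1 (-2.44) and Krt80 (-1.76), and 18 when the subtraction was paired, while Wfdc18 (-0.36), Rarres1 (-0.51), Wfdc17 (-0.44), Cidea (-0.20) and Far2 (-0.15) changed sign. The count was 455 at a minimum of 2-fold, 1855 by DESeq2's test, 1696 with only the compared groups, 1875 without the back total library of few genes, and 95, 481, 601 and 74 without Slc1a3+ replicate 1, Slc1a3+ replicate 2, Dlx1+ replicate 1 or Dlx1+ replicate 2. Rarres1, Wfdc17, Far2, Rasgrp1, Fst, Dpysl3, Susd2, Il20ra and Krt7 passed with any of these left out. Scaled by library totals 1499 genes passed, 191 higher and 1308 lower, among them 191 of the 404 higher and all 553 lower genes above, and by limma-voom 1130, 658 higher and 472 lower.

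**Figure D4:**
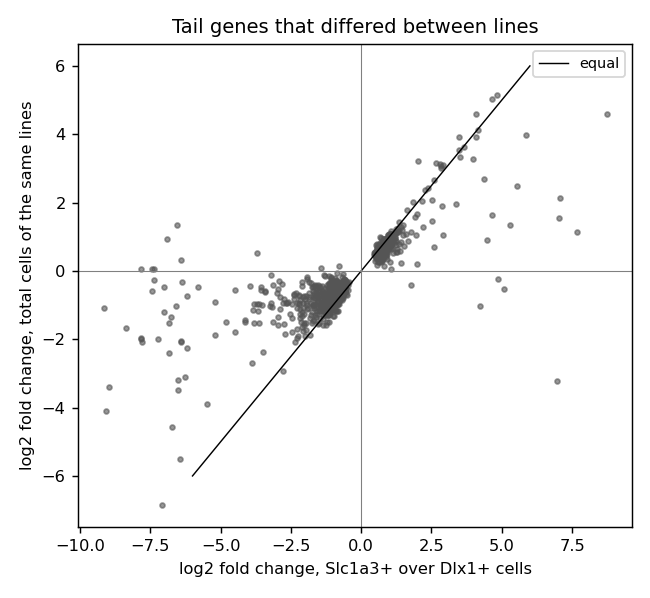
Log2 fold change of the 957 genes that passed between tail Slc1a3+ and Dlx1+ cells (horizontal axis) and of the same genes between the total IFE of the 2 lines (vertical axis). Of the points, 943 have the same sign on both axes, and Susd2 (-3.58 and -0.46) and Il20ra (-3.22 and -0.13) lie near 0 on the vertical axis.

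Tail Aspm+ cells differed from Dlx1+ cells in upper follicle, sebaceous and differentiation genes, among others. Rarres1 was higher in Aspm+ cells (9.79 CPM, SD 1.35, n = 2, against 0.346, SD 0.199, n = 2), a log2 change of 4.70 (SE 0.469, adjusted p = 1.06e-05). Asprv1, a protease of the granular layer, rose by 3.71, Klk7, a desquamation protease, by 3.30 and Far2 by 2.74. Angel1 fell by 1.43 and Pkn3 by 1.06. Of 21 upper follicle and sebaceous genes 3 were higher (Cst6 2.41, Krt79 1.74, Cidea 2.74) and 8 when adjusted over the list alone, with a median of 1.31 (camera adjusted p = 6.02e-23, and 0.00448 with an estimated correlation). Of 34 differentiation genes 2 were higher (Asprv1 and Elovl4, 2.12) and 14 when adjusted over the list alone, with a median of 0.67 (adjusted p = 5.67e-19, and 0.00168 with an estimated correlation). Of 20 genes of stressed or wounded keratinocytes 0 passed over all genes and 3 were higher when adjusted over the list alone (adjusted p = 6.49e-04, and 0.0334 with an estimated correlation). All 28 ribosome genes were positive, with a median of 0.45 and 0 passing (adjusted p = 2.39e-17, adjusted p = 0.154 with an estimated correlation). In all 15 lists passed by camera with the fixed correlation. Among lists not described, anagen matrix and inner root sheath genes had a median of 1.77, or 1.72 with members at their bound. Langerhans and myeloid genes had 1.82, or 1.30, and axon guidance and glutamate transport genes -0.11.

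In that comparison 16 genes passed, 14 higher and 2 lower, with 983 at an unadjusted p under 0.05, the totals differed in 6, and all 16 had the same sign there. The totals gave medians of 0.90 for the upper follicle list, 0.51 for the differentiation list and 0.252 for the ribosome list. With each line's total subtracted these medians were 0.372, -0.002 and 0.179, and 0 genes passed (edgeR, paired or not). The count was 159 without a low-count filter, 87 by DESeq2's test, 36 by limma-voom, 179 with only the compared groups and 44 without the back total library of few genes, and 10, 3, 1 and 1 without Aspm+ replicate 1, Aspm+ replicate 2, Dlx1+ replicate 1 or Dlx1+ replicate 2. Only Rarres1 kept its call with any of these left out.

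Tail Slc1a3+ and Aspm+ cells were compared last within a site, and most genes that passed were lower in Slc1a3+ cells. Il20ra measured 0.941 CPM (SD 0.0962, n = 2) in Slc1a3+ and 13.1 (SD 0.563, n = 2) in Aspm+ cells, a change of -3.79 (SE 0.302, adjusted p = 5.84e-08), and Susd2 3.43 (SD 0.576) and 35.4 (SD 5.13), a change of -3.36. Rasgrp1 changed by -4.47, Fst and Pappa by -3.29, Col8a1 by -3.20, Dpysl3 by -3.04, Maob, a monoamine oxidase, by -2.89, Pnpla3 by -2.86 and Krt7 by -2.68. Higher in Slc1a3+ cells were Wnt6, a Wnt ligand (24.1 CPM, SD 4.24, against 9.89, SD 1.49, log2 1.29), Isoc2b (1.82), Npr3 (1.75), Cpxm2 (1.17), Fgfbp1 (1.08), the metallothionein Mt1 (1013 CPM, SD 5.97, against 506, SD 42.6), Tnfrsf12a (0.85), Nop9 (0.84), Sphk2 (0.79) and Tjp3 (0.67). All 28 ribosome genes were positive, with a median of 0.45 and 0 passing over all genes or adjusted over the list alone (adjusted p = 5.46e-11, adjusted p = 0.902 with an estimated correlation). The lines' totals gave 0.572 for the same median, and with each line's total subtracted it was -0.132. In all 86 genes passed, 13 higher and 73 lower, with 2030 at an unadjusted p under 0.05. The totals differed in 1 gene, and 79 of the 86 had the same sign there.

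With each line's total subtracted 7 genes passed in that comparison, all lower, Susd2 (-3.26), Il20ra (-3.32), Rasgrp1 (-3.57), Man1a (-2.66), Col23a1 (-2.54), Adh7 (-2.29) and Krt80 (-1.79), and 35 when the subtraction was paired, while Sphk2 turned to -0.05. The count was 142 scaled by library totals, 408 without a low-count filter, 303 by DESeq2's test, 27 by limma-voom, 695 with only the compared groups and 171 without the back total library of few genes, and 21, 30, 20 and 42 without Slc1a3+ replicate 1, Slc1a3+ replicate 2, Aspm+ replicate 1 or Aspm+ replicate 2. With any of these left out Rasgrp1, Il20ra, Susd2 and Maob kept their calls, whereas each of the 10 higher genes named lost its call in at least 1 case. By limma-voom Rasgrp1 and Maob did not pass.

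The total IFE of back and tail was compared over the 8 back and 6 tail totals. The largest changes toward the tail, which bears scales, included hard keratins. Krt84 measured 0.640 CPM (SD 0.919, n = 8) in back and 1662 (SD 622, n = 6) in tail, a log2 change of -11.43 (SE 1.29, adjusted p = 1.53e-06), and Krt36 0.611 (SD 0.704) and 1469 (SD 610), a change of -11.07. Krt77, a type II keratin, measured 2132 CPM (SD 584) and 3.54 (SD 1.63), a change of 9.32 (SE 0.292, adjusted p = 2.08e-17), and Skint7, of a family expressed in skin and thymus, 119.8 (SD 40.6) and 0.0446 (SD 0.0534), a change of 10.99. H2-Q7, a class I gene, measured 304 CPM (SD 68.7) and 0.505 (SD 0.260), a change of 9.26, and the class I gene H2-Q5 was 2330 times higher in back (interval 645 to 19200). Pkib (10.01), Iigp1, an interferon-induced GTPase (9.45), Lama1, a laminin chain (9.14), Tgm7, a transglutaminase (9.10) and Cfap57 (8.80) were also higher, and Mrgprb11-ps 1380 times (381 to 11400). Lower in back were Mettl7a3 (-11.19), Hoxd11 (-11.10), Hoxd9 (-9.75), Fam20a (-9.75), Tmem117 (-9.68), Hoxc11, with 0 counts in back (at least 63.7-fold), Olah (2130 times, 382 to 84100) and Hhip, a Hedgehog inhibitor (909 times, 251 to 7520).

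The Hox genes, which encode position along the body axis, split by site. Of 14 posterior Hox genes 13 were lower in back, among them Hoxc13 (-6.61) and Hoxd8 (-8.42), and Hoxc8 was higher (5.16), with adjusted p = 2.88e-25, and 2.46e-04 with an estimated correlation. Of 18 anterior and central Hox genes 15 were higher (Hoxc4 4.12, Hoxc6 3.35, Hoxa5 2.82), and Hoxd4 was lower (-6.42), with adjusted p = 4.05e-07, and 0.0127 with an estimated correlation. Of 23 interferon response genes 21 were higher (Psmb8 5.47, Usp18 5.43, B2m 5.13, Psmb9 4.88), with a median of 3.70, or 3.53 with 1 member at its bound, and adjusted p = 1.36e-17 and 0.0428 with an estimated correlation. B2m lay between 562 and 2660 CPM in the 16 back libraries and between 30.3 and 76.7 in the 12 tail libraries. These counts were the same when adjusted over the list alone.

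Follicle genes were lower in back. Of 20 bulge and germ genes 15 were lower in back (Krt24 -5.33, Cd34 -3.99, Gas1 -1.88) and 1 higher, Krt15 (2.05), which held 17000 CPM in back totals and 4140 in tail totals. Of 21 upper follicle and sebaceous genes 15 were lower (Elovl3 -7.31, Cidea -6.29, Krt79 -2.45, Plin2 -1.70) and 2 higher, and of 12 fibroblast markers 5 were lower and 1 higher. The adjusted p of these 3 lists with an estimated correlation was 0.0428, 0.0428 and 0.0274. Of 21 genes of scale-type hard keratins and their regulators 13 were lower (Krt35 -5.79, Msx2 -1.54) and 1 higher, Edaradd (1.29), a signal adaptor of the ectodysplasin receptor, with adjusted p = 0.00242, and adjusted p = 0.313 with an estimated correlation. Their median was -3.45. Anagen matrix and inner root sheath genes had a median of -5.40, or -4.55 with members at their bound. Of 30 mitosis genes 18 were lower (Cdca3 -1.87, Plk1 -1.87, Cdc20 -1.38, Ccnb1 -1.21), with adjusted p = 6.34e-07, and adjusted p = 0.348 with an estimated correlation. Of 22 immediate early genes 10 were higher and 3 lower (adjusted p = 0.0379, adjusted p = 0.406 with an estimated correlation). Adjusted over the list alone, 16 upper follicle and 15 hard keratin genes were lower and the other counts were the same.

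Slc1a3 itself measured 20.1 CPM (SD 3.56, n = 8) in back totals and 9.0 (SD 2.02, n = 6) in tail totals, a change of 1.19 (adjusted p = 5.91e-07), Krt14 14930 (SD 5470) and 34240 (SD 8000), a change of -1.15, and Dlx1 0.539 and 8.74 (SD 1.09), a change of -4.66. Back Slc1a3 total replicate 4 alone held 2.94 CPM of Dlx1, and without back Aspm total replicate 1 the change became -6.11. Aspm did not pass (-0.33, adjusted p = 0.190). In all 7955 genes passed, 4027 higher and 3928 lower in back, with 9046 at an unadjusted p under 0.05, and 3699 at a minimum of 2-fold, and every gene named by the rule passed with any of the 14 totals left out.

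**Figure D5:**
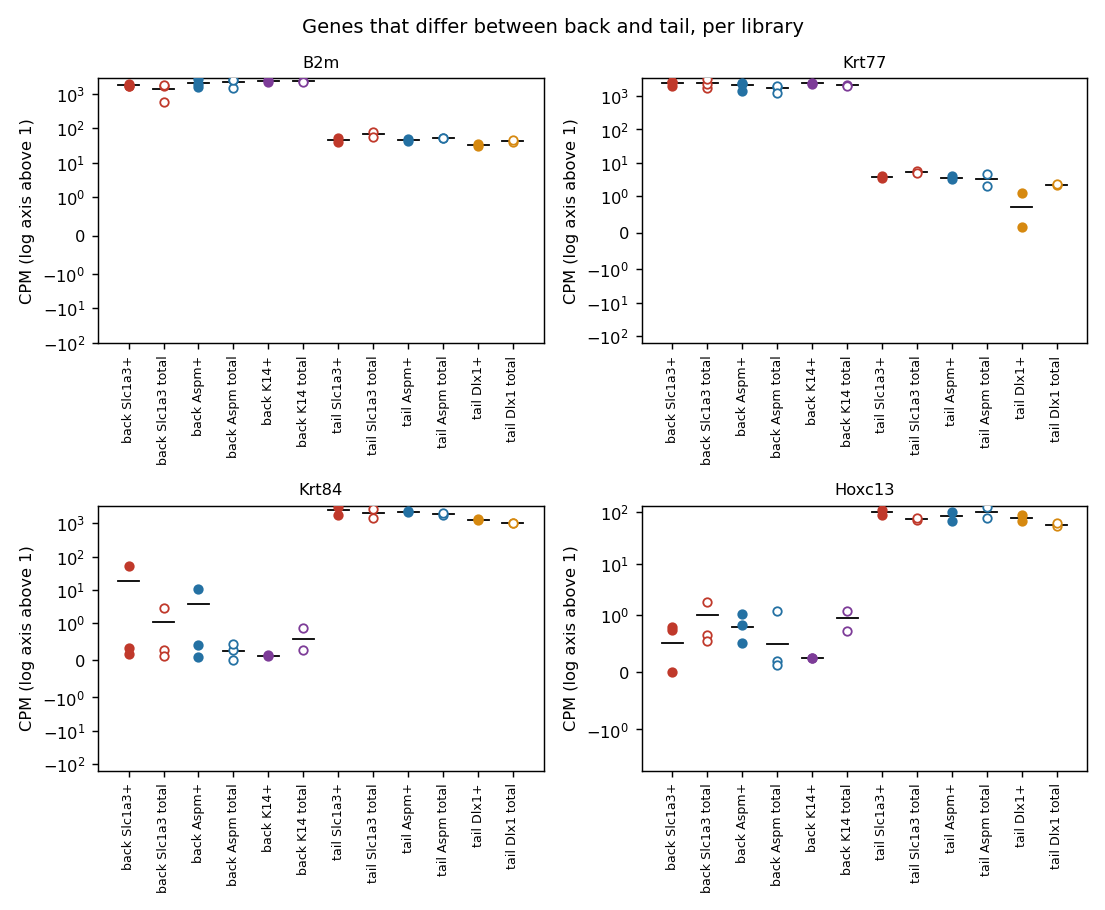
Level of named site genes in each of the 28 libraries (points, CPM on a log axis), grouped by site. B2m lies between 562 and 2660 CPM in back libraries and between 30.3 and 76.7 in tail libraries.

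The sites were also compared in labelled cells. In Slc1a3+ cells, back against tail, Clca3a1, Lama1, Pkib and H2-Q5 had 0 counts in tail and were at least 472-fold, 416-fold, 311-fold and 224-fold higher in back. Wfdc17 was 1900 times lower (interval 649 to 9210), and Ugt8a, a galactosyltransferase of lipid synthesis, Hoxc11 and Serpinb3d, at 0 in back, at least 42.7-fold, 34.6-fold and 28.2-fold lower. Of 14 posterior Hox genes 12 were lower and 1 higher (adjusted p = 2.51e-16, and 3.49e-05 with an estimated correlation). All 28 ribosome genes were lower, with a median of -1.16 (adjusted p = 1.97e-14, adjusted p = 0.262 with an estimated correlation). Of 23 interferon genes 17 were higher, and 19 when adjusted over the list alone (adjusted p = 4.69e-11, adjusted p = 0.262 with an estimated correlation).

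In this comparison 7104 genes passed, 3776 higher and 3328 lower, with 8619 at an unadjusted p under 0.05. With each site's total subtracted 16 passed (15 higher, 1 lower), and 83 when paired (77 higher, 6 lower), and Hoxc11 turned to 0.77 from levels at the floor and Slc1a3 to -0.74. The count was 4317 at a minimum of 2-fold and 4660 without tail Slc1a3+ replicate 1, and scaled by library totals 4742 were higher and 2482 lower.

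In Aspm+ cells H2-M3, Mrgprb11-ps and Pyy, at 0 counts in tail, were at least 201-fold, 161-fold and 127-fold higher in back, and H2-Q7 4560 times (interval 1260 to 37600). Wfdc17, Hoxd11, Hoxd3os1 and Hoxd10, at 0 in back, were at least 414-fold, 372-fold, 218-fold and 162-fold lower. Of 14 posterior Hox genes 12 were lower and 1 higher, and 13 and 1 when adjusted over the list alone (adjusted p = 4.24e-28, and 8.81e-06 with an estimated correlation). Of 23 interferon genes 16 were higher, and 17 when adjusted over the list alone (adjusted p = 5.34e-15, adjusted p = 0.0758 with an estimated correlation). In all 4766 genes passed, 2545 higher and 2221 lower, with 6692 at an unadjusted p under 0.05. With each site's total subtracted 0 passed (edgeR, paired or not), and the label genes Slc1a3 (-0.47), Dlx1 (0.69) and Aspm (0.47) changed sign. The count was 2875 at a minimum of 2-fold, 2973 without tail Aspm+ replicate 1 and 2741 without tail Aspm+ replicate 2.

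Whether the difference between Slc1a3+ and Aspm+ cells itself differed between sites was tested as an interaction. Rasgrp1 measured 0.264 CPM (SD 0.121, n = 2) in tail Slc1a3+ and 5.88 (SD 3.57, n = 2) in tail Aspm+ cells, against 114.9 (SD 16.2, n = 3) and 117.9 (SD 25.6, n = 3) in back, a difference of 4.43 on the log2 scale (SE 0.601, adjusted p = 6.53e-04). Il20ra differed by 3.61 (SE 0.351, adjusted p = 3.24e-06), Cgn, a tight junction protein, by 4.19 and Srgap1 by 3.84. Aqp3, a water and glycerol channel, measured 43.7 CPM (SD 5.92) in back Slc1a3+ and 80.8 (SD 11.9) in back Aspm+ cells, against 1738 (SD 187) and 1403 (SD 60.3) in tail, a difference of -1.19, and Pwp1 differed by -0.91. Of 22 immediate early genes, which respond within minutes to stimuli and to tissue dissociation, 2 were higher, Dusp1 (2.7, adjusted p = 3.77e-04) and Egr1 (3.15, adjusted p = 0.0375), and 7 when adjusted over the list alone, with a median of 0.78. All 28 ribosome genes were negative, with 0 passing over all genes and 27 lower when adjusted over the list alone, and a median of -0.93. Both lists passed by camera (adjusted p = 1.63e-06 and 3.82e-26), and both gave adjusted p = 0.197 with an estimated correlation. Between the lines' totals, Slc1a3 against Aspm, the ribosome median was -0.353 in back and 0.572 in tail. With each line's total subtracted the medians of labelled cells were -0.128 and -0.132. The totals also differed by 0.517 in back and -1.113 in tail for Dusp1, and by 1.064 and -1.387 for Egr1, which did not pass. A background of the lines thus cannot be told apart from lineage here.

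In the interaction 24 genes passed, 22 higher and 2 lower, with 2506 at an unadjusted p under 0.05. With the totals subtracted 2 passed, Susd2 (3.48) and Il20ra (3.29), and 6 when paired. The count was 131 scaled by library totals, 524 without a low-count filter, 378 by DESeq2's test, 4 by limma-voom, 10 with only the compared groups and 242 without the back total library of few genes. It was 47, 13 and 9 without back Slc1a3+ replicate 1, 2 or 4, 98 and 14 without back Aspm+ replicate 1 or 4, 10 without tail Slc1a3+ replicate 1 and 8 without tail Aspm+ replicate 1, and Rasgrp1 and Il20ra passed with each library left out. Scaling by library totals moved the median of all genes by 0.15 for back Slc1a3+ against K14+, -0.19 for tail Slc1a3+ against Dlx1+, -0.11 for tail Slc1a3+ against Aspm+, 0.20 for Slc1a3+ cells between sites and 0.20 in the interaction.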

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

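The tests of depth for the bulge and germ genes, of the line background, and of the exchanges within pairs were written before their results, and all other tests in this part were chosen after the result was seen, the test of scaling in a later form after its counts of shared genes had been read. A test for values far from the others of their site was run on 98 values among the totals, and 16 lay far out. About 1 in 20 would by chance if values followed a normal curve, which levels resting on a few counts do not.

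The back Slc1a3 total replicate 4 had 14436 genes with a count, where the other 7 back totals had 19265 to 21347. Its mitochondrial share was 0.208%, against 1.389 to 1.983 in the others. It held Dlx1 at 2.937 CPM (others 0 to 0.507) and H2-Q5 at 74.57 (15.16 to 40.24). The back Slc1a3 total replicate 2 held 5 genes of the tail above the other back totals. These were Krt84 at 2.821 CPM (0 to 0.879), Krt36 at 2.265 (0 to 0.667), Mettl7a3 at 1.539 (0 to 0.362), Tmem117 at 0.1282 (0 to 0.0351) and Olah at 0.04274 (0 in the others). Tail genes also had counts in back K14 total replicate 4, with Hoxd11 and Fam20a both at 0.1449 (others 0 to 0.0676), and in back Aspm total replicate 1, with Hhip at 0.07021 (0 in the others). Levels this low rest on very few counts, as the back totals held 1 count of Olah and 2 of Hhip. Psmb9 in back Aspm total replicate 2 was low at 59.13 (96.02 to 125.0). Tail Aspm total replicate 2 held Hoxc13 at 126.2 (54.87 to 76.74) and Tgm7, a back gene, at 0.5268 (0 to 0.197). Hoxd8 in tail Slc1a3 total replicate 2 was 48.66 (63.87 to 68.63).

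The difference between Slc1a3+ and Aspm+ cells was not the same in both sites for 24 genes, among them Rasgrp1 (4.426), Cgn (4.187), Srgap1 (3.843), Il20ra (3.608), Aqp3 (-1.192) and Pwp1 (-0.906). With the 3 lines of a site fitted together, the difference of labelled cells from their total was not the same in tail and back for 109 genes.

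Bulge and germ genes were lower in labelled tail cells of each line. Over the 3 tail lines together the median was -1.182 with 18 of 20 members negative, and in back -0.356 with 16 negative. Random genes of the same mean level over all 28 libraries seldom fell as far. A share of 0.01% or less of 10000 such lists did (the lowest 2.5% of them began at -0.123). Level was matched over both sites and genes were drawn singly, so the test cannot exclude low counts in tail. Depth was not varied. Follicle cells in the total gate that are absent among labelled cells are a candidate explanation and fit the value of -1.182, which restates the pattern and does not part it from others. Markers of other cells went both ways in labelled tail libraries. Vwf (0.367 against 2.79 CPM), Krt8 (0.279 against 2.77), Cck (0.110 against 2.05) and Epcam (22.8 against 48.3) were lower. Gpnmb (385 against 336), Rora (166 against 141), Thy1 (65.8 against 56.7) and Tnni2 (5.76 against 2.86) were higher. The rises of Gpnmb, Rora and Thy1 were small beside these falls, and the kind of cell stays open.

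Differences between lines in labelled cells were present in the totals to a degree that varied with the lines. For the 957 genes of tail Slc1a3+ against Dlx1+ cells, the change between totals was 0.765 of the change between labelled cells (median), which fits a difference between mouse lines or litters carried by all their cells. The totals contain labelled cells in an unknown share, which could also raise this ratio of 0.765. For back and tail Slc1a3+ against Aspm+ cells the ratio was only 0.439 and 0.253, over 28 and 86 genes. Genes picked for passing in labelled cells tend to have overestimated changes there, which lowers these ratios. How much of those differences a line background accounts for thus stays open. Scaling by library totals moved the median of all genes by -0.189. The median change of the 404 higher genes went from 0.854 to 0.667 (quartiles 0.53 and 0.86), and 191 still passed. A shift of nearly the same size in all genes fixes that fall in advance, so scaling as a cause stays undecided for them. For the 553 lower genes (median -1.325) the shift goes their way and decides nothing.

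Interferon and class I genes were higher in back skin. Immune cells in the back gate could not be told from keratinocytes, since 29 immune markers rose together by 0.0699 of the rise of B2m, between the bounds of 0.05 and 0.2 set for the test. Between the 5 back libraries with fewest and most immune counts (ratio 0.665), B2m had a ratio of 1.04. With 2 further markers left out after their levels were seen the ratios were 0.391 and 0.867. The latter meet the bounds set against immune cells, though the choice of markers came after the fact. All 16 back libraries, labelled ones included, held at least 562 CPM of B2m, against at most 76.7 in the 12 tail libraries. The labels name no batch, and a difference between the sites themselves was not tested apart from these and stays open.

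Libraries were also divided in other ways and fitted again. Back Slc1a3+ against total called 19 genes in the real division, and 1 of 10 divisions, the real one, reached that. The next called 16, the 4 divisions that part every pair called 0 apart from the real one, and 10 divisions are too few for a share under 0.05. Back Aspm+ against total called 0 by edgeR, which all 10 reached, and the highest other called 3. Back Slc1a3+ against Aspm+ called 28 in the real division, reached by 1 of 10, and the others called 0. The totals of those 2 lines called 2, reached by 2 of 10 divisions. Total IFE between sites, fitted on the 14 totals alone, called 6719 genes, reached by 1 of 100 divisions, and the highest other called 1. Exchanges of labelled and total within pairs gave 1 of 32 for the tail lines together (1897 genes on the tail libraries alone, highest other 539) and 1 of 100 for the back lines together (43 genes, highest other 16).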

How the results depend on the processing

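The alternatives were fixed in advance except for the library of few genes left out, the block without it, and the subtraction with the block, which were chosen after the result was seen. Counts of genes that passed are given below for each setting that moved them by more than 1.5 times, and values of named genes where the direction turned. The cause of these shifts was not tested. The counts for site held best, whereas those of labelled cells against their total and between lines moved with most settings. Direction was the same for nearly all named genes in each setting that keeps the question the same, and most of those that turned are label genes that did not pass or lie near 0 counts.

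Without a low-count filter the counts against the total became 135 (back Slc1a3+), 27 (back Aspm+), 42 (back K14+), 276 (tail Slc1a3+), 26 (tail Aspm+) and 95 (tail Dlx1+). Between lines they became 255 (back Slc1a3+ against Aspm+), 979 (back Slc1a3+ against K14+), 342 (back Aspm+ against K14+), 159 (tail Aspm+ against Dlx1+) and 408 (tail Slc1a3+ against Aspm+), and 524 in the interaction. With DESeq2's test they were 43, 2, 12, 195, 5 and 34 against the total in the same order, 161, 1258, 151, 87 and 303 between the same lines, 1855 for tail Slc1a3+ against Dlx1+ and 378 in the interaction. With limma-voom they were 9 (back Slc1a3+ against total), 0 (back K14+), 52 (tail Slc1a3+), 0 (tail Aspm+), 29 (tail Dlx1+), 12 (back Aspm+ against K14+), 36 (tail Aspm+ against Dlx1+), 27 (tail Slc1a3+ against Aspm+) and 4 (interaction).

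With only the compared groups in the fit the counts were 0 (back Slc1a3+ against total, edgeR), 11 (back K14+), 3 (tail Aspm+), 12 (tail Dlx1+), 4 (back Slc1a3+ against Aspm+), 1598 (back Slc1a3+ against K14+), 179 (tail Aspm+ against Dlx1+), 695 (tail Slc1a3+ against Aspm+), 1696 (tail Slc1a3+ against Dlx1+) and 10 (interaction). At a minimum of 2-fold they were 142 (back Slc1a3+ against K14+), 455 (tail Slc1a3+ against Dlx1+), 3699 (total IFE), 4317 (Slc1a3+ cells between sites) and 2875 (Aspm+ cells between sites). Scaled by library totals they were 3 (tail Dlx1+ against total), 142 (tail Slc1a3+ against Aspm+), 1499 (tail Slc1a3+ against Dlx1+) and 131 (interaction).

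The replicate block gave 62 (back Slc1a3+ against total), 18 (back K14+), 261 (tail Slc1a3+), 6 (tail Aspm+) and 81 (tail Dlx1+), and without the library of few genes the block gave 88, 39, 523, 41 and 212, and 8 for back Aspm+. Between lines, where pairing has no ground, the block gave 82 (back Slc1a3+ against Aspm+), 863 (back Slc1a3+ against K14+), 66 (back Aspm+ against K14+), 35 (tail Aspm+ against Dlx1+), 179 (tail Slc1a3+ against Aspm+), 1643 (tail Slc1a3+ against Dlx1+) and 245 (interaction). Other than the lists named in the report, the block changed no call of a list in a comparison with the total. Without the library of few genes and without the block the counts were 115, 1403 and 60 for the 3 back pairs of lines, 44, 171 and 1875 for the tail pairs (Aspm+ against Dlx1+, Slc1a3+ against Aspm+, Slc1a3+ against Dlx1+), 15 for tail Dlx1+ against total and 242 in the interaction.

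With each line's or site's own total subtracted, 0 genes passed by edgeR for back Slc1a3+ against Aspm+, both comparisons with K14+, tail Aspm+ against Dlx1+ and Aspm+ cells between sites, 4 for tail Slc1a3+ against Dlx1+, 7 for tail Slc1a3+ against Aspm+, 16 for Slc1a3+ cells between sites and 2 in the interaction. The subtraction with the block gave 6, 0 (edgeR), 0, 0, 0, 18, 35, 83 and 6. Named genes that turned under the subtraction are given with the value of the subtraction followed by that of the blocked subtraction. Back Slc1a3+ against Aspm+ turned for Nr4a1 (-0.051, -0.026), Tent5b (0.100, 0.091), Dlx1 (-1.188, -0.751) and Aspm (-0.065, -0.131). Back Slc1a3+ against K14+ turned for Gypc (2.565, 2.995), Esr1 (0.182, 0.142) and Vcp-rs (0.121, 0.045), and back Aspm+ against K14+ for Gypc (4.661, 5.137), Aspm (0.181, 0.217) and Krt14 (0.055, 0.043). Tail Slc1a3+ against Dlx1+ turned for Wfdc18 (-0.360, -0.481), Rarres1 (-0.512, -0.617), Wfdc17 (-0.438, -0.464), Cidea (-0.200, -0.202), Far2 (-0.153, -0.188) and Krt14 (-0.018, -0.019), and for Serpinb3d with the block alone (-0.079). Tail Aspm+ against Dlx1+ turned for Slc1a3 (0.061, 0.075) and Krt14 (-0.076, -0.076), and tail Slc1a3+ against Aspm+ for Sphk2 (-0.052, -0.044). Between sites Slc1a3+ cells turned for Hoxc11 (0.765, 0.767) and Slc1a3 (-0.738, -0.733), Aspm+ cells for Slc1a3 (-0.467, -0.473), Dlx1 (0.694, 1.02) and Aspm (0.467, 0.512), and the interaction for Dlx1 (-1.898, -1.462) and Aspm (-0.043, -0.114).

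Values of Dlx1 in back skin are fitted near 0 counts and cannot be read as folds. Krt14, which did not pass within a site, passed in 5 settings for back Slc1a3+ against K14+ (-0.798 without a low-count filter, -0.781 by DESeq2's test, -0.827 with only the compared groups, -0.753 with the block and -0.831 without the library of few genes). It passed in 2 for tail Slc1a3+ against Dlx1+ (0.658 without the filter, 0.695 without that library), and without the filter for back Aspm+ against K14+ (-0.541) and in the interaction (-0.754). Aspm passed in 3 settings for tail Slc1a3+ against Dlx1+ (-1.057 without the filter, -1.014 with only the compared groups, -0.965 with the block). Dlx1, near 0 counts, passed in 3 for back Slc1a3+ against K14+ (without the filter, by DESeq2's test, without the library of few genes) and in 1 for back K14+ against total (without the filter). Slc1a3 passed for Slc1a3+ cells between sites when scaled by library totals (0.633). The label genes that turned in other settings did not pass in any of those. For back Slc1a3+ against total these were Dlx1 with limma-voom (0.291), without the library of few genes (1.595) and with the block besides (2.014), Krt14 in the same 2 fits (0.151 and 0.073) and Aspm in the last (-0.012). For back Slc1a3+ against K14+ they were Slc1a3 with limma-voom (-0.031) and the block (-0.024) and Aspm with the block (-0.070). For back K14+ against total Aspm turned with DESeq2 size factors (-0.011), library totals (-0.028), the strict filter (-0.012) and DESeq2's test (-0.012), and for back Aspm+ against total Slc1a3 turned with limma-voom (0.014).

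With each library left out in turn, the counts ran from 9 to 19 for back Slc1a3+ against total, 0 to 1 for back K14+, 29 to 51 for tail Slc1a3+, 0 to 1 for tail Aspm+ and 0 to 2 for tail Dlx1+. Between lines they ran from 9 to 37 (back Slc1a3+ against Aspm+), 9 to 528 (back Slc1a3+ against K14+), 8 to 31 (back Aspm+ against K14+), 74 to 601 (tail Slc1a3+ against Dlx1+), 1 to 10 (tail Aspm+ against Dlx1+) and 20 to 42 (tail Slc1a3+ against Aspm+). Between sites they ran from 4660 to 6634 (Slc1a3+), 2741 to 4541 (Aspm+) and 8 to 98 (interaction). Label genes that turned ran as follows. Against the total these were Aspm (-0.004 to 0.313), Dlx1 (-1.473 to 1.595) and Krt14 (-0.654 to 0.151) in back Slc1a3+, Aspm (-0.121 to 0.519), Dlx1 (-2.271 to 4.737), Krt14 (-0.050 to 0.257) and Slc1a3 (-0.179 to 0.070) in back Aspm+, Slc1a3 (-0.106 to 0.256) and Aspm (-0.170 to 0.198) in back K14+, and Aspm (-0.494 to 0.480) in tail Dlx1+. Slc1a3 ran from -0.147 to 0.227 for back Slc1a3+ against K14+ and from -0.606 to 0.039 for tail Aspm+ against Dlx1+, and Aspm from -0.320 to 0.057 for Aspm+ cells between sites.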

Other observations

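The fits of the 3 lines together and the reading of the Rosa locus below were chosen after the single comparisons were seen. With the replicate block and the 3 lines of a site together, 444 genes passed for tail labelled cells against their totals, 64 higher and 380 lower. Lrig1 was lower in all 6 tail pairs (45.95 against 114.9 CPM), a log2 change of -1.66. Ccn2, a matrix protein gene driven by YAP and TGF-beta, measured 9.94 and 59.2 CPM, a change of -2.68. Fst changed by -2.07, Foxc1 by -1.88, Sox9 by -1.68, and the Wnt receptor Fzd7 by -1.50. These values average lines that differ, since Lrig1 measured 10.6 against 83.3 CPM in the Slc1a3 line, 62.7 against 104.1 in the Aspm line and 64.6 against 157.4 in the Dlx1 line. Higher were Slc1a3 (0.70), Igfbp3 (0.66), Npl (0.48) and the Wnt ligands Wnt7b (0.39) and Wnt3 (0.36).

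In back skin 78 genes passed, 4 higher and 74 lower. Ltbp1 changed by -2.28, Fst by -1.63 in all 8 pairs, Sostdc1 by -1.33, Tnc by -1.25, Sox9 by -1.06 and Krt17 by -0.75, and Lrig1 by only -0.35 (198.5 against 249.4 CPM). Both sites shared 57 genes, all in the same direction and 55 of them lower. By chance 1.61 would be lower in both if all tested genes were equally likely to pass. Genes differ in level and spread and both results come from 1 fit, so this number may be too low. Between tail and back 109 genes differed, among them Usp18 (-3.17), Rasgrp1 (-2.22), Susd2 (-1.32) and Lrig1 (-1.31), with Kif26a (1.73), Tnc (1.08) and Aqp3 (0.89) the other way. The tail Slc1a3 line carries much of the difference for 3 of these, as Susd2, Rasgrp1 and Lrig1 differed by -3.27, -3.52 and -2.23 between tail Slc1a3+ and Aspm+ cells with their paired totals subtracted. The value of Usp18 is fitted near 0 counts, since the 12 tail libraries held 0 to 1.15 CPM. Tail Slc1a3+ cells held 3 counts of it against 28 in their total, 7.95 times lower (interval 2.46 to 40.9).

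Gt(ROSA)26Sor, read from the locus that carries the reporter, was higher in the labelled library in 14 of 14 pairs, by ratios of 1.11 to 6.74, and 3 of these pairs are the ones that led to its being read. In back skin it measured 28.8 CPM in labelled cells and 14.4 in totals (adjusted p = 0.00957). The reporter itself is not among the genes of the files.

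The bulge and germ list passed with an estimated correlation in all 3 tail lines and in 0 of the back lines by camera, though with paired libraries back K14+ cells passed too (0.0141), and no test compared the list between sites. A further hypothesis is that labelled IFE cells 2 weeks after tamoxifen hold few cells of follicle origin, in line with the pooled median of -1.182 in tail. Counts of the same sort with a follicle marker such as Cd34 stained beside tdTomato, or single-cell sequencing, would test it.

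Susd2 and Il20ra were low in tail Slc1a3+ cells against their own total and against both other lines. Between the totals of the Slc1a3 and Dlx1 lines they differed by -0.46 and -0.13, against -3.58 and -3.22 between the labelled cells, while Rasgrp1 was lower there too (-1.49, adjusted p = 0.0272). Whether they mark a state of the tail Slc1a3+ cells could be followed in tissue, and the ratio of 0.765 for the genes of that comparison as a whole may serve as the yardstick. Litter mates that carry different CreER lines would be needed to part line from lineage.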
